A study of Homo sapiens with 12 samples.

How the data were processed

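The series holds 12 ATAC-seq libraries of MDA-MB-453 cells, 1 for each of 3 ER forms and 4 treatments, sequenced as 75 bp paired ends on 1 or the other of 2 Illumina instruments, per the labels' protocols, which do not say which library ran on which. For each library the authors deposited 1 peak list with hg38 coordinates. Per the submitters' processing notes, FastQC, Bowtie2, SAMtools, Picard and MACS2 were used; their versions and settings, including any shift of reads for the transposase cut, are not given in the sources used here. Peaks were called per library, without pooling and without a control library, and an interval could hold several summits. In the deposited lists the score is 10 times the −log10 q without its decimals. The deposited fold enrichment is the ratio of the summit pileup plus 1 to the background plus 1. The deposited −log10 p and −log10 q values belong to the summit pileup under a Poisson background. These are the authors' values for single peaks and served to rank or filter peaks within a list.

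Every fold in a library was a whole multiple of 1 step, so the summit pileup and the single background of that library could be recovered. The pileups came out whole to within 0.000772, and a Poisson tail above the pileup gave the deposited −log10 p to a median difference of at most 1.5e-05. The background ranged from 0.143 to 0.442 and stands for depth; totals of reads are not used here. The lowest pileup of a listed peak was 3 to 5, so a region without a peak had a pileup under about that level and is not shown to be closed. Summits on other sequences (54 to 114 per library) were left out of the comparisons.

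Peaks of all libraries were merged where they overlapped by 1 bp or more into 166523 regions. A region was called open in a library with at least 1 peak in it. A region was Dox-gained in an ER form when open in both libraries with Dox and in neither of the others, and Dox-lost in the reverse case. Peaks per library, shared regions and the share near gene ends were tested by exact permutation of the Dox or E2 labels within ER forms (216 arrangements). Counts of shared regions and overlaps were tested one-sided, other values two-sided. Shares of regions carry exact (Clopper-Pearson) 95% intervals, which cover counting error only. Benjamini-Hochberg adjustment covered the 10 main tests of library values and, separately, the 8 genes fixed in advance.

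Gene positions came from a RefSeq table of GRCh38.p14, the assembly family of hg38, with 13 gene lists fixed in advance. The table gives gene spans without strand or exons. Distances to a transcription start, as planned, were therefore replaced by distances to either end of a protein-coding gene (1 kb), and gene list windows reach 50 kb beyond the span. All list genes were matched, 1 of them through an older symbol. Each list's count of genes with a gained or lost region was placed among 10000 random lists matched on the number of regions. Windows of neighbouring list genes overlap, so a region can count for several genes, and the matching does not allow for this. Motif comparisons that had been planned need the genome sequence and were not run.

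Named regions followed a rule fixed before the data were examined. It takes, per ER form, the 10 gained and the 10 lost regions with the largest smaller −log10 q of the libraries where they are open, with the nearest gene end given within 100 kb or the gene around the summit. It takes the 10 shared Dox-gained regions with the largest smallest −log10 q, or all where there are 20 or fewer, and the 5 strongest regions open only with Dox+E2 in each form. It also takes listed genes with changes in the same direction in at least 2 forms, of which examples are given, and genes fixed in advance (ESR1, GREB1, TFF1, PGR, FOXA1, GATA3 and FKBP5 among 8 tested). A gene of that set and a region that the rule selects are not reported here.

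The alternatives chosen in advance were stricter −log10 q thresholds (5 and 10), equal list length by −log10 p, summits within 501 bp windows, peaks covering at least 50% of a region, each ER form left out, a 2500 bp distance and gene windows of 20 and 100 kb. Equal list length means 39522 peaks in every library, except in the within-form counts, where it is the length of the form's shortest list. Chosen after seeing the data were thinning of pileups to equal signal over the 16630 regions open in all libraries (pileup of at least 5 kept), a single length of 39522 for all libraries in the within-form counts, leaving out single libraries, equal list length for the genes fixed in advance, overlap of libraries at a −log10 q of 5 or more, named regions at a −log10 q of 10 or more and thinned, swaps of labels within the 6 matched pairs (same ER form and same other treatment), and the lookup of Y537S regions in other lines. The counting was tested on simulated libraries drawn for the 166523 regions: with no changed regions 1 was called, and of 200 changed 20-fold 146 were recovered. The changed regions were drawn only among those with high pileups, and no differences by line or run were simulated. The shared Dox-gained regions had median pileups of 6 to 10 in WT and K303R with Dox (23 in Y537S). With no changed regions the highest other arrangement gave 17, against 121 in the data, so the simulation is the more favourable case. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.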

Results

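Chromatin accessibility was measured by ATAC-seq, in which a transposase cuts open chromatin and inserts sequencing adapters there. The cells were MDA-MB-453, an established human breast cancer line. Each of 3 engineered lines carried a doxycycline-inducible, ectopic estrogen receptor alpha (ER), either wild type (WT), Y537S or K303R. Y537S is a mutation of the ligand-binding domain known for activity without estrogen, and K303R lies in the hinge region. Each line was left untreated, given 1 nM estradiol (E2), given doxycycline (Dox, 2 ug/mL) or given both for 2 days, which makes 12 libraries with 1 library per ER form and treatment. There were no replicates, so Dox and E2 were tested over the 3 ER forms together, and within a form values are described without a test. Nothing in the labels says that the 12 cultures were independent beyond their treatment, so p-values measure only the spread between these libraries.

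The peak lists held 47190, 78022, 82091 and 64476 peak summits in the WT libraries (untreated, E2, Dox, Dox+E2) on chromosomes 1 to 22 and X. They held 106291, 118631, 132496 and 133963 in the Y537S libraries, and 39522, 61723, 97243 and 102713 in the K303R libraries. The background pileup, which scales with the number of fragments, ranged from 0.143 in WT untreated to 0.442 in K303R untreated. The untreated K303R library stood apart: its median summit pileup over the 16630 regions open in all 12 libraries was 24.9 times its background, against 47.1 to 102 times in the other 11. Peak names carried 3 tags, which are taken here as runs; what the tags record is not given in the sources used here, and statements about runs rest on this reading. Of the forms only WT is written in the peak names. The Y537S names hold the word trypsin, which the others lack, so the ER forms of these libraries rest on the labels. By the tags, all Y537S libraries shared 1 run, all K303R libraries shared another run with WT untreated and WT E2, and both WT libraries with Dox came from the remaining run. Dox and run therefore cannot be separated in WT, whereas every Dox comparison within Y537S and K303R, and every E2 comparison, lay inside 1 run.

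The first comparison asked where chromatin opened with induction of the receptor whatever its form. Regions near TRPC6, a cation channel gene, CACNG4, a calcium channel subunit gene, SERPINA1, which encodes alpha-1 antitrypsin, and inside PLXNA2, a semaphorin receptor gene, were open in all 6 Dox libraries and in none of the 6 without Dox. There were 2165 such regions among 166523, and 4 with the opposite pattern. The region 9.60 kb from an end of TRPC6 (hg38, chromosome 11, 101441443 to 101442566) had summit pileups of 52 and 34 in WT with Dox and with Dox+E2, 93 and 90 in Y537S, and 38 and 23 in K303R, and no peak in the other libraries. The region 31.1 kb from CACNG4 (chromosome 17, 66933099 to 66934354) reached 38 and 30 in WT, 90 and 78 in Y537S, and 25 and 24 in K303R. The region inside PLXNA2 (chromosome 1, 208068635 to 208069874) reached 29 and 38, 78 and 81, and 23 and 34 in the same order. The others of the 10 with the largest smallest −log10 q lay inside OTUD7B (chromosome 1, 150017102 to 150018124), inside CD34 (chromosome 1, 207890207 to 207891337), inside FAM13C (chromosome 10, 59322808 to 59323699), 0.404 kb from SERPINA1 (chromosome 14, 94390435 to 94391244), 86.2 kb from PPP1R26 (chromosome 9, 135392279 to 135392995), 35.4 kb from LOC124901498 (chromosome 6, 163676166 to 163677140) and in a stretch of chromosome 8 with no gene end within 100 kb (133806433 to 133807303). Of the 2165 regions, 50.8% had their summit inside a protein-coding gene and 3.14% (68 regions, exact 95% interval 2.45 to 3.96%) within 1 kb of a gene end. EPAS1, SHANK2, GPHN and TMEM229B had 6 such regions each within 50 kb, the most of any gene, among 46, 324, 114 and 50 regions of any kind there, and the count is not adjusted for these totals. These 4 genes were picked after their counts were seen, and TMEM229B lies within the span of GPHN, so their regions overlap. The 4 regions lost in every form lay near GUCA2A (chromosome 1, 42169586 to 42170333), near ADAM30 (chromosome 1, 119893199 to 119893722) and at 2 places on chromosome 20 far from genes, with smallest −log10 q of 2.62 to 4.81.

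No other arrangement of the Dox labels within ER forms gave as many regions as the 2165 (exact permutation test, one-sided, p = 0.00463, the smallest that the arrangements of labels within forms can give), and the highest other arrangement gave 121. The count of regions lost was not exceptional (4 regions, exact permutation p = 0.134, one-sided). When every library was limited to its 39522 strongest peaks, 326 regions were gained and 158 lost (exact permutation p = 0.00463 and 0.00926, one-sided). Leaving out a library loosens the rule: without K303R Dox 3870 regions were gained, and 43, 30, 24, 19, 15 and 7 were lost without K303R untreated, K303R Dox+E2, K303R Dox, WT untreated, K303R E2 and WT Dox.

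Estradiol gave no such shared regions. None of the 166523 regions was open in all 6 E2 libraries and without a peak in the other 6, and none showed the reverse (exact permutation p = 1 for each, one-sided). The rule asks for a change with E2 both with and without Dox, so an E2 effect that needs the induced receptor could not be counted. In simulated libraries this kind of rule recovered 146 of 200 regions changed 20-fold and 4 of 200 changed 4-fold. These simulated regions had high pileups, where a 4-fold change can leave a peak in place. Recovery of weaker regions was not measured. The shared Dox-gained regions had median pileups of 6 to 10 in the WT and K303R libraries with Dox. The lowest listed pileup in the WT and K303R libraries without Dox was 3 to 5. Near that level a small change can meet the rule, so the simulation does not give the smallest change found.

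Within Y537S, Dox went with the largest number of changed regions. Here 30358 regions were open in both Dox libraries and in neither of the others, and 11178 showed the reverse, while the remaining ways of pairing the 4 libraries gave 659 to 1465. The strongest gained region lay inside TFRC, the transferrin receptor gene (chromosome 3, 196055004 to 196056663), with pileups of 149 and 136 and no peak in Y537S without Dox (WT E2 and untreated K303R had 6 each). It was followed by regions inside WNT9A, a Wnt ligand gene (chromosome 1, 227934466 to 227936302, pileups 124 and 146), inside CASKIN2 (chromosome 17, 75507767 to 75510229, 116 and 133), inside SHANK2, a synaptic scaffold gene (chromosome 11, 71201710 to 71204138, 123 and 116), and inside HHAT, an acyltransferase gene of hedgehog signalling (chromosome 1, 210649067 to 210650158, 139 and 114). The others lay 81.2 kb from RGS9 (chromosome 17), inside ARVCF (chromosome 22), 3.36 kb from MYOG (chromosome 1), 10.7 kb from OPTC (chromosome 1) and near TRPC6. The strongest lost regions lay inside TNR, ABCC1, GRIK4, OR9Q1, ATP8A2, MDN1 and STS, 86.4 kb from WNT7A, and at 2 places on chromosomes 4 and 21 with no gene end within 100 kb. Their smaller −log10 q ranged from 41.0 to 54.9. Without the untreated library 22383 regions were lost, and without E2 17343.

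Within WT, 6892 regions were gained and 3462 lost with Dox. The strongest gained regions lay 3.36 kb from MYOG, a muscle transcription factor gene (chromosome 1, 203088655 to 203090218, pileups 47 and 39), near TRPC6, inside WNT9A (34 and 49), inside SHANK2 (34 and 58), inside TTC7A (chromosome 2, 47032849 to 47033854, 33 and 34), near CACNG4, inside MAPK14, which encodes a p38 kinase (chromosome 6, 36118242 to 36119042, 34 and 27), and inside PLXNA2. The other 2, on chromosomes 14 and 17, had no gene end within 100 kb. The strongest lost regions lay near LRATD2 (chromosome 8, 126579646 to 126580800), CUL2, MRPL14, THEM6 and TYRO3, inside NFASC, UNC5C and IL17REL, and at 2 places on chromosomes 13 and 16 away from genes, with smaller −log10 q of 15.2 to 24.8. The other pairings of the WT libraries gave 174 to 4652 regions. The largest of these, open with E2 alone and Dox alone but not in the others, joined the 2 WT libraries with the most peaks. Without E2, Dox and Dox+E2 in turn, 11543, 14512 and 18096 regions were gained, and without untreated, E2 and Dox 14697, 6919 and 8069 were lost; without the untreated library losses outnumbered gains (7370 gained).

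Within K303R, 14222 regions were gained and 133 lost. The lowest listed pileup was 5 untreated and 4 with E2, but 3 with Dox and with Dox+E2. A region with a pileup of 3 throughout could thus count as gained. Of the 14222 regions, 48.7% were open in untreated Y537S and 14.5% in untreated WT. With Dox, 64.6% were open in Y537S and 57.3% in WT. The strongest gained regions given here lay near CACNG4 (pileups 25 and 24), near TRPC6 (38 and 23) and inside OTUD7B (23 and 23). Further regions lay inside PLXNA2, TRABD2B, GAB2 and CACNA1D, 14.5 kb from PANX1 and 10.2 kb from RNF139. The lost regions were weak (smaller −log10 q of at most 11.3) and lay inside RASSF5, ASAP1, RSPRY1, GRID2IP, FBXO25 and P2RY6, near SPN, ADAM30 and VDR, and at 1 place on chromosome 13 with no gene end within 100 kb. With libraries limited to equal length, which moves gains and losses towards balance, K303R had 1628 gained and 1661 lost. Without the untreated library, which had the lowest signal in this form, 15466 were gained and 2397 lost. Without E2 the counts were 26135 and 2515, without Dox 33760 and 397, and without Dox+E2 29588 and 499. At equal list length WT had 3313 gained and 4265 lost, and Y537S 21808 and 14095. No p-value within 1 form can fall below 0.167.

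**Figure D1:**
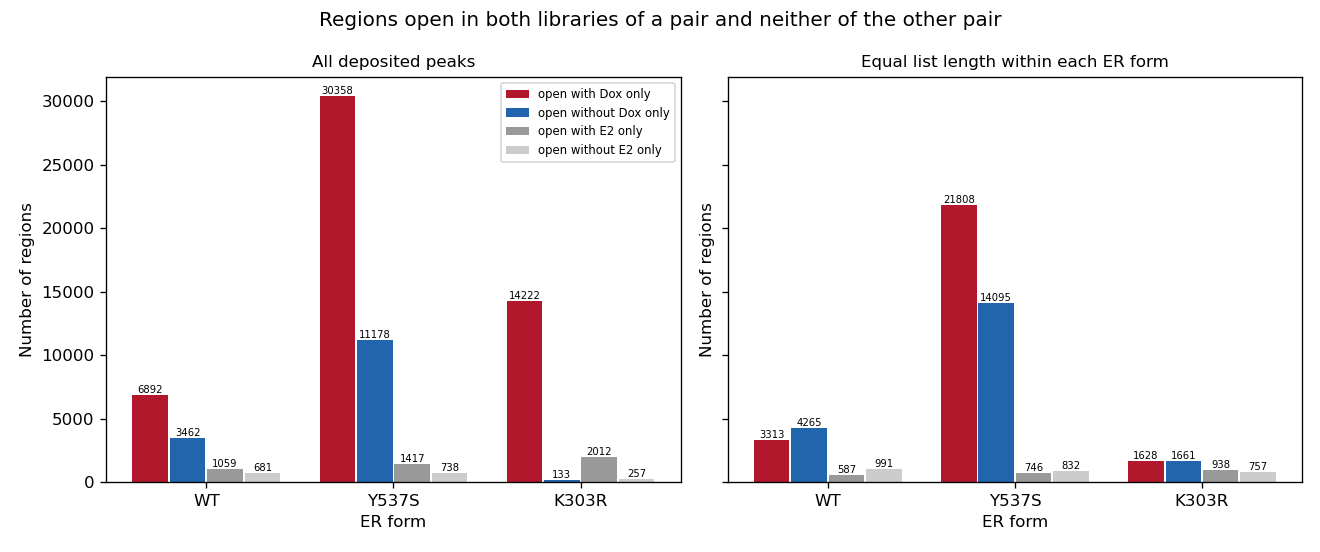
Number of regions (vertical axis) open in both libraries of a pair and in neither of the other 2 libraries, for each ER form (horizontal axis), with all peaks on the left and each form's libraries cut to equal length on the right. In Y537S the Dox pairing gave 30358 and 11178 regions with all peaks and 21808 and 14095 at equal length, against 1417 or fewer for the E2 pairing; the K303R excess of gains (14222 against 133) was absent at equal length (1628 against 1661).

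Most gained and most lost regions lay away from gene ends. In WT 5.56% of the gained regions had a summit within 1 kb of a gene end (exact 95% interval 5.03 to 6.12%), in Y537S 3.65% (3.44 to 3.87%) and in K303R 7.83% (7.39 to 8.28%). Of the lost regions 4.25%, 5.12% and 8.27% did in the same order, and of regions open in all 4 libraries of a form 38.6%, 26.5% and 32.0%. With 39522 peaks per library the gained shares were 11.6%, 4.36% and 15.3%, the lost shares 6.81%, 11.3% and 7.89%, and those of regions open in all 4 were 48.6%, 48.0% and 40.1%. The lists gained by different forms shared members: 4758 regions were gained in both WT and Y537S, against 1256 for independent lists among the 166523 regions. WT and K303R shared 2964 (589 for independent lists), and Y537S and K303R shared 3410 (2593 for independent lists). These independent values are too low, since 53210 of the 166523 regions were open in only 1 library. Such regions can be gained or lost in no form. The small excess for Y537S and K303R with all peaks therefore cannot be read as sharing. In the opposite direction, 1237 regions were lost in Y537S and gained in K303R, against 955 on the same low baseline. The direction of this difference varied with the setting. It was 95 against 151 with 39522 peaks per library, 497 against 518 at a −log10 q of 5 or more, and 94 against 79.4 when thinned. Of the WT-gained regions, 69.0% were also gained in Y537S and 43.0% in K303R. These shares fell to 53.6% and 16.4% with 39522 peaks per library, and to 47.4% and 14.0% when thinned.

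The next comparison concerned E2 in cells already given Dox. The regions that separated Y537S with Dox from Y537S without it were used as a reference and looked up in the WT and K303R libraries. With 39522 peaks in every library, 24.8% of the 8490 Y537S-gained regions were open in WT with Dox (exact 95% interval 23.9 to 25.7%) and 54.6% in WT with Dox+E2 (53.6 to 55.7%). Without Dox, 5.89% were open in untreated WT and 4.03% with E2. In K303R the shares were 13.2% with Dox (12.5 to 13.9%) and 22.9% with Dox+E2, against 6.45% and 4.65% without Dox. Of the 5924 Y537S-lost regions, 42.1% were open in WT with Dox and 24.6% with Dox+E2, against 71.6% in untreated WT. In K303R the lost regions were open in 63.0% with Dox and 60.9% with Dox+E2. With all peaks the gained shares rose from 22.7% to 34.4% in WT and from 15.4% to 34.8% in K303R. The lost shares with all peaks were 20.1% in untreated WT, 41.5% with E2, 18.3% with Dox and 4.09% with Dox+E2, so Dox alone lay close to untreated, and in K303R 12.1%, 32.0%, 46.6% and 46.3%. This lookup was chosen after the data were seen, its intervals cover counting error over regions only, and each share comes from 1 library.

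**Figure D2:**
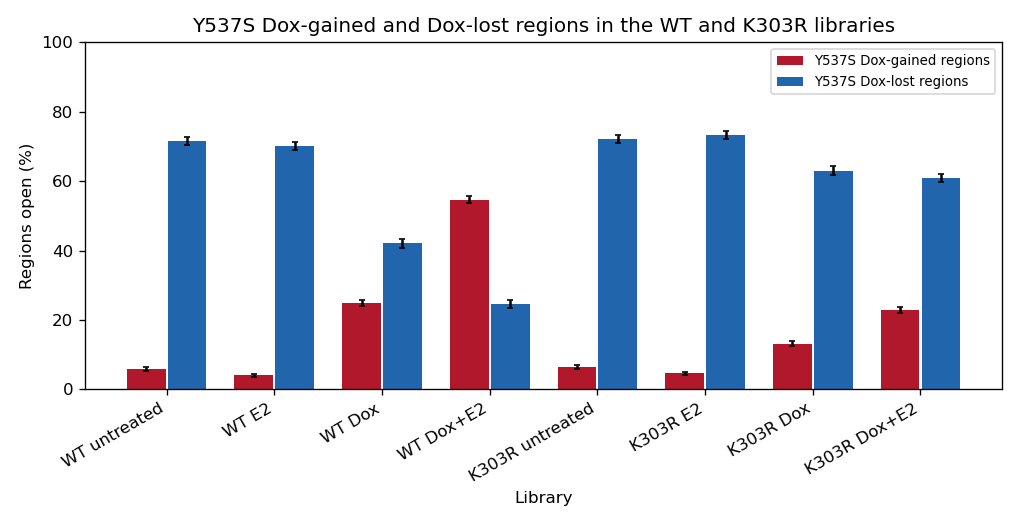
Percent (vertical axis) of the 8490 Y537S Dox-gained and 5924 Y537S Dox-lost regions that were open in each WT and K303R library (horizontal axis), with 39522 peaks in every library. Error bars are exact 95% binomial intervals over regions. WT with Dox+E2 had 54.6% of the gained and 24.6% of the lost regions, and K303R with Dox+E2 had 22.9% and 60.9%.

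Single regions were open with Dox+E2 alone in each form. In WT the 5 strongest lay inside NTNG1 (chromosome 1, 107401889 to 107402683), RNF215 (chromosome 22, 30382442 to 30383842) and PAPLN (chromosome 14, 73260647 to 73262599), near ZNF669 (chromosome 1, 247090183 to 247091054), and on chromosome 14 away from genes. The NTNG1 region had a pileup of 24 in WT with Dox+E2 and of 55 and 39 in Y537S with Dox and with Dox+E2. In K303R they lay inside ASAP1 (chromosome 8, 130348379 to 130349807, pileup 22, against 86 and 115 in Y537S) and LLGL2, near ZDHHC19, and at 2 places on chromosomes 1 and 6. In Y537S they lay inside TANC2, NOP14 and KCNH1, near SSX2IP, and on chromosome 11 away from genes, and 4 of these 5 had a peak in no other library. Of all 7620 regions open only with Dox+E2 among the WT libraries, 83.5% were open in Y537S with Dox (exact 95% interval 82.6 to 84.3%), whereas 38.1% of the 11204 open only with Dox were (37.2 to 39.0%). For K303R the shares were 53.1% of 19538 (52.4 to 53.8%) and 23.4% of 15366 (22.7 to 24.0%). In untreated Y537S the same shares were 10.7% and 24.8% for WT, and 22.1% and 24.7% for K303R. With all peaks, regions open only with Dox in K303R were thus no more often open in Y537S with Dox than without. The equal-length shares were 61.0% of 5387 and 18.2% of 3012 for WT, and 44.7% of 3019 and 19.0% of 2703 for K303R.

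Estrogen response genes, a list fixed before the data were examined, often had gained regions within 50 kb. In WT 31 of the 50 had one, the 95.9th percentile of 10000 random lists matched on the number of regions (median 25). In K303R 46 of 50 did (99.9th percentile, median 38), and in Y537S 43 of 50 (52.2nd percentile, median 43). With 39522 peaks per library the counts were 20 in WT (98.4th percentile), 17 in K303R (99.8th) and 29 in Y537S (83.8th). The WT value was not particular to this list, since immediate early genes (12 of 23, 99.2nd) and housekeeping genes (11 of 23, 98.2nd) stood as high there. Neighbours such as TFF1, TFF3 and TMPRSS3 can share regions, and the percentiles do not allow for this. Of the 50 genes, 30 had a gained region in all 3 forms and 41 in at least 2, counts that were not placed among random lists; other lists reached similar shares (14 of 23 immediate early genes in all 3 forms, 20 of 24 luminal identity genes in at least 2). The carbonic anhydrase gene CA12 had 7 gained regions in WT, 17 in Y537S and 6 in K303R. The receptor tyrosine kinase gene RET had 5, 19 and 7, the cathepsin D gene CTSD 5, 12 and 2, FHL2 6, 11 and 6, NHERF1 8, 8 and 4, and SERPINA1 8, 6 and 4. Single lost regions lay near CTSD in WT, near RET, FHL2 and NHERF1 in Y537S and near NHERF1 in K303R. XBP1, AREG, AMIGO2 and AGR3 had lost regions in WT and Y537S. XBP1 and AREG also had 1 gained region each in Y537S, and in K303R XBP1, AMIGO2 and AGR3 had 1, 2 and 3 gained regions.

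Among the genes fixed in advance, GREB1, an estrogen-induced ER cofactor gene (chromosome 2, 11482888 to 11642788), had 13.2 ± 5.38 open regions within 50 kb in the Dox libraries and 6.67 ± 3.93 in the others (SD, n = 6 each; exact permutation p = 0.00926, two-sided, adjusted 0.0370 over the 8 genes tested). It had 4, 10 and 2 gained regions in WT, Y537S and K303R, and 2 lost in Y537S. TFF1, a secreted trefoil peptide gene (chromosome 21, 42362282 to 42366535), had 9.50 ± 4.32 and 4.17 ± 1.72 (exact permutation p = 0.00926, adjusted 0.0370), and PGR, the progesterone receptor gene (chromosome 11, 101029624 to 101129813), 10.5 ± 2.51 and 4.50 ± 3.15 (exact permutation p = 0.0185, adjusted 0.0494). The co-chaperone gene FKBP5 (chromosome 6, 35573590 to 35728583) had 10.2 ± 3.60 and 7 ± 2.53 (exact permutation p = 0.0278, adjusted 0.0556). FOXA1, a pioneer factor gene of luminal cells (chromosome 14, 37589552 to 37595249), had 13.8 ± 3.25 and 11 ± 3.22 (exact permutation p = 0.148), and GATA3 (chromosome 10, 8045333 to 8075198) 10.0 ± 6.20 and 7.50 ± 7.48 (exact permutation p = 0.111). With labels swapped only within matched pairs GREB1 and TFF1 reached the smallest possible p before adjustment (exact permutation p = 0.0312 each) and PGR and FKBP5 missed 0.05 (exact permutation p = 0.0625 each). With equal list length none of the genes given here passed 0.05 (GREB1, 1.5 more regions with Dox, exact permutation p = 0.0556), and the difference turned negative for FOXA1 and FKBP5.

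ESR1, the gene of the receptor itself (chromosome 6, 151656672 to 152129619), had 11.3 ± 4.27 open regions within 50 kb with Dox and 6.33 ± 3.01 without (SD, n = 6 each; exact permutation p = 0.0556, two-sided). With equal list length the difference was 0.167 regions (exact permutation p = 1, two-sided). Of the 22 regions inside the gene, 1 was open in all 12 libraries (151763167 to 151764716) and none separated the 6 Dox libraries from the rest. A region at 151944227 to 151944575 was open in WT with Dox and Dox+E2 (pileup 6 in each) and in Y537S with Dox and Dox+E2 (7 and 9) and in no other library, K303R included; it was singled out after its values were seen. Exon positions were not used here, so whether such peaks cover exons of the receptor was not resolved.

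Of the other lists, interferon genes had gained regions near 12 of 22 in WT (99.3rd percentile), 17 of 22 in Y537S (79.0th) and 11 of 22 in K303R (17.5th), with IFI6, OAS2 and CXCL10 among those with gains in all forms. They had 8, 13 and 5 at equal list length (97.0th, 97.1st and 87.8th), and 7, 15 and 8 with 20 kb windows (95.4th, 97.3rd and 42.1st). Neighbours such as OAS1, OAS2 and OAS3 can share regions, which the random lists do not allow for. Immediate early genes had 14, 18 and 20 of 23 (92.7th, 22.4th and 94.5th percentile), with 6, 9 and 3 regions near FOSL2, which also had 2 lost in Y537S, and 4, 6 and 4 near JUND. Their counts were 12, 13 and 7 with 39522 peaks per library (99.2nd, 56.3rd and 90.6th) and 12, 13 and 16 with 20 kb windows (98.7th, 8.60th and 93.6th). Luminal identity genes had 13, 20 and 22 of 24 (23.9th, 5.46th and 88.3rd), and GRHL2, an epithelial transcription factor gene, had 4, 10 and 6, and 2 lost in Y537S. At equal list length 11 of the 24 luminal genes had a gained region in Y537S, at the 0.18th percentile. Androgen and apocrine genes had 12, 22 and 19 of 26 (52.6th, 69.2nd and 64.0th). The MAPK feedback list had 5, 9 and 10 of 14 (34.0th, 10.4th and 64.2nd), the stress response list 9, 14 and 12 of 22 (59.2nd, 7.24th and 12.4th), and the cell cycle list 6, 17 and 9 of 20 (34.2nd, 94.0th and 8.03rd). Housekeeping genes had 13, 18 and 15 of 23 (88.6th, 24.9th and 22.9th). Limited to 39522 peaks per library, the stress response list had 4, 13 and 8 of 22 (24.4th, 87.6th and 98.9th), the cell cycle list 1, 5 and 1 of 20 (2.67th, 5.28th and 11.2th), and the housekeeping list 11, 15 and 5 of 23 (98.2nd, 85.0th and 65.3rd). For lost regions, the estrogen list stood low in WT (9 of 50, 3.22nd percentile), and the housekeeping list high in Y537S (18 of 23, 97.7th). These were 13 of 50 (18.5th) and 7 of 23 (5.74th) at equal list length. Over 78 such counts, 3.90 would lie outside the central 95% of random lists by chance; 4 did, and 8 did at equal list length: gained regions of the estrogen list in WT and K303R, of the immediate early and housekeeping lists in WT, of the luminal list in Y537S and of the stress response list in K303R, and lost regions in WT of the immediate early list (3 of 23, 1.12th) and the basal list (10 of 22, 97.7th).

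Of the 24 luminal identity genes, 21 to 24 had a summit within 1 kb of a gene end in each library, and of the 26 androgen and apocrine genes 11 to 21 did. Lists of other cell types had fewer: 4 to 9 of 22 basal and myoepithelial genes, 2 to 8 of 22 mesenchymal genes, 2 to 8 of 20 immune genes and 2 to 7 of 20 neuronal and hepatic genes. The basal list had gained regions near 10, 19 and 12 genes in WT, Y537S and K303R (68.8th, 92.1st and 14.3rd percentile), with MYLK at 1, 13 and 3 gained and 3, 3 and 0 lost regions. The mesenchymal list had 4, 13 and 5 (40.0th, 72.8th and 1.49th; in K303R 2 at equal list length, 61.3rd, and 4 with 20 kb windows, 11.4th), the immune list 6, 13 and 11 (59.0th, 46.8th and 49.4th), and the neuronal and hepatic list 6, 16 and 10 (25.6th, 94.5th and 20.3rd).

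Libraries of the same Dox state overlapped more on average, while grouping by ER form was not separated from run. At equal list length the Jaccard index of shared base pairs averaged 0.468 for pairs with the same Dox state and 0.407 for pairs that differed (exact permutation p = 0.00926, one-sided, the smallest possible); with all peaks the averages were 0.432 and 0.372, with the same p. It averaged 0.463 within an ER form and 0.423 between forms (exact permutation p = 0.0365 over 5775 groupings, one-sided), and 0.423 and 0.444 for the same and different E2 state (exact permutation p = 0.806, one-sided). The groupings of forms ignore run: by the tags, in a comparison chosen after seeing the data, pairs of the same run averaged 0.478 within a form (14 pairs) and 0.477 between forms (8 pairs), and pairs of different runs 0.411 (4 pairs) and 0.413 (40 pairs). The nearest pairs were Y537S untreated with Y537S E2 (0.667) and Y537S Dox with Y537S Dox+E2 (0.634). WT with Dox+E2 overlapped Y537S with Dox by 0.459, more than WT with Dox did (0.404). The average did not hold for every pair. WT Dox, K303R Dox and K303R Dox+E2 overlapped untreated Y537S (0.465, 0.532 and 0.529) more than Y537S of the same treatment (0.404, 0.374 and 0.407). Only WT Dox+E2 went the other way (0.394 against 0.463). By the tags, Dox and run also coincide in WT.

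**Figure D3:**
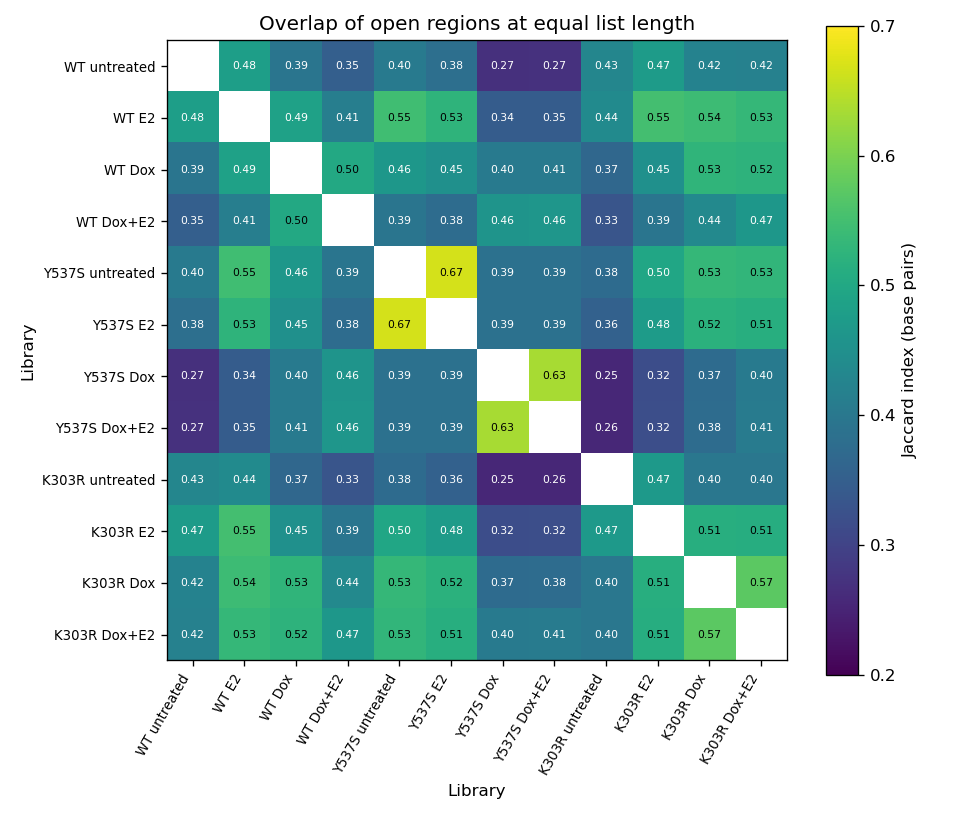
Jaccard index in base pairs (colour, printed in each square) for each pair of the 12 libraries (both axes), each cut to 39522 peaks. The brightest squares are the Y537S pairs that differ in E2 alone (0.667 and 0.634), and the darkest lie between Y537S with Dox and untreated K303R (0.255 and 0.256).

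Dox libraries had more peaks. They held 102164 ± 27492 peaks against 75230 ± 31937 without Dox (SD, n = 6 each; exact permutation p = 0.0185, two-sided; 0.185 after Benjamini-Hochberg adjustment over 10 tests), and more in 5 of the 6 matched pairs (same ER form and E2 state); WT with Dox+E2 had fewer than WT with E2. With labels swapped only within these pairs, a test chosen after seeing the data, the difference missed 0.05 (exact permutation p = 0.0625 over 64 arrangements, two-sided). The call ended with stricter peak thresholds (exact permutation p = 0.111 at a −log10 q of 5 or more) and held after thinning to equal signal, chosen after seeing the data (6360 more peaks with Dox, exact permutation p = 0.00926, two-sided, the smallest possible). E2 libraries held 93255 ± 29816 against 84139 ± 35668 (exact permutation p = 0.454, two-sided). Y537S libraries held 54900 more peaks than WT (122845 against 67945, n = 4 each; exact permutation p = 0.0286, two-sided, the smallest that 70 arrangements can give), and K303R 7356 more (exact permutation p = 0.714). Each form is 1 line, and Y537S is also 1 run, so these describe lines rather than receptors.

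At equal list length, 37.9 ± 3.71% of peaks in Dox libraries and 38.4 ± 3.01% in the others had a summit within 1 kb of a gene end (SD, n = 6 each; exact permutation p = 0.815, two-sided). The share in Y537S fell by 8.11 points with Dox, while it rose by 3.77 in WT and by 3.08 in K303R. The Y537S and WT effects differed by 11.9 points, with WT higher (exact permutation p = 0.0556, two-sided, the smallest that 36 arrangements allow). E2 alone changed the equal-length share over untreated by 4.45 points in WT, 3.53 in K303R and −0.992 in Y537S, so the rises were not particular to Dox. With all peaks the Dox effect was a drop in each form (−0.210 points in WT, −6.48 in Y537S and −7.54 in K303R).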

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

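The tests of splits, thinning, run, doxycycline alone, signal, the untreated K303R library, list length, depth and list sensitivity below were chosen only after the results were seen, and so were the limits that decide them. At equal list length the share of peaks near gene ends moved in opposite directions with Dox in different ER forms. In both matched pairs it fell in Y537S (mean change −8.11 points) and rose in WT (3.77) and in K303R (3.08). With all peaks the mean change was a drop in each form (−0.210 points in WT, −6.48 in Y537S and −7.54 in K303R). The Y537S against WT difference reached p = 0.0556 by exact permutation, the smallest its 36 arrangements allow, so the design cannot pass 0.05. The Y537S against K303R difference was not tested. E2 alone changed the equal-length share over untreated by 4.45 points in WT, 3.53 in K303R and −0.992 in Y537S. With E2 in both libraries, Dox added 2.32 points in WT and 1.51 in K303R. The untreated WT and K303R lists were the shortest, and that of K303R was not cut. The rises therefore cannot be assigned to Dox alone.

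On 2 of 16 sequences outside the main chromosomes every Dox library had more peaks than every other library; the other 14 did not separate. On a sequence assigned to chromosome 17 without a known position, Dox libraries had 11.7 ± 2.42 peaks and the others 3.67 ± 1.51 (SD, n = 6 each), a difference of 8 peaks with every Dox library above every other. On a sequence assigned to no chromosome they had 9.83 ± 2.23 against 4.83 ± 1.72, a difference of 5 peaks. Both reached p = 0.00926 by exact permutation, the smallest possible, and an adjusted p of 0.0741 over the 16 sequences examined.

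Counting a split of the libraries and its mirror as 1, only 1 of 108 splits, the real one, gave as many regions as the 2165 open in all 6 Dox libraries and in none of the others. The highest other split gave 121. Chance is thus unlikely, but with 1 library per condition it is not excluded. Depth or signal is argued against by the thinned libraries, where 257 regions remained against 23 for the highest other split. If the tags in peak names mark runs, all Y537S libraries shared 1 run, and so did all K303R libraries. Run therefore cannot set Dox apart within these forms. Every split of their libraries is balanced for run, so the counts for splits do not test run. At equal list length 487 regions followed Dox against 143 for the highest other of 18 splits (482 against 99 when thinned). These settings were reached after the values were seen: with all peaks 3410 against 1237 missed a first criterion of 3 times the highest other split. The criterion was then relaxed, and the comparison was at last moved to equal length under the first criterion. The reason was that with all peaks both counts exceeded independent lists alike (2593 and 955). That baseline is too low, since it includes regions open in only 1 library. For WT, run and Dox cannot be told apart (6892 gained regions), since the libraries with Dox came from their own run by the tags. An effect of doxycycline acting without the receptor also stays open, since 0 libraries of a line without the receptor were analysed here.

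The excess of gained over lost regions in K303R (14222 against 133) may come from differences in signal among its libraries. After thinning to equal signal the gained count was 1.34 times the lost count in K303R, whereas in Y537S it was 3.29 times. Whether the untreated library alone brings it about stays open: without that library 15466 regions were gained and 2397 lost, 6.45 times as many, so part of the excess stayed. List length cannot be told apart from signal: at equal length the ratio was 0.98, but equal lengths push gains and losses towards balance by themselves, and a first reading that counted this value for list length was withdrawn after it was seen. No biological explanation for the K303R excess was tested beyond this.

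The Y537S-gained regions were, at equal list length, more often open in WT with Dox+E2 (54.6%) than with Dox (24.8%), which itself lay above untreated WT (5.89%). Greater depth is argued against: the Dox+E2 library had the lower background (0.253 against 0.361) and fewer peaks, and after thinning the difference was 22.4 points. A more sensitive list would raise the share of Y537S-lost regions as well. At equal length that share moved by −17.5 points, but fixed lengths force part of this, since added peaks displace others. With all peaks the lost share also fell, from 18.3% to 4.09%, while the gained share rose from 22.7% to 34.4%. These values argue against a more sensitive list in WT, and both libraries carry the same tag. In K303R the Y537S-lost regions moved little (63.0% with Dox, 60.9% with Dox+E2), so a more sensitive list stays open there. A candidate explanation for WT is that E2 adds to the regions of this set that WT ER opens, a hypothesis found and examined on the same libraries, with 1 library per condition.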

How the results depend on the processing

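Chosen after seeing the data were the thinning, the common length of 39522 in within-form counts, single libraries left out, the Y537S lookup under every setting, equal list length for single genes, swaps of labels within matched pairs, overlap of libraries at a −log10 q of 5 or more, and named regions at a −log10 q of 10 or more; the rest were planned. Motif alternatives were not run. Replicate numbers pair no libraries, but each ER form gives matched pairs that share the other treatment. With labels swapped within these 6 pairs (64 arrangements), the Dox effect on peaks (26934) lost its call (exact permutation p = 0.0625), as did those for PGR and FKBP5, while the shared Dox-gained regions (2165) kept it at the smallest p possible, 0.0156 (exact permutation). The cause of a change was not tested unless stated.

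The Dox effect on peaks per library kept its direction but missed 0.05 with a −log10 q of 5 or more (13874 peaks), 10 or more (8548), without WT (35062), without Y537S (30016) and without K303R (15723), the last 3 with 36 arrangements, which cannot pass 0.05. The Dox effect on the share near gene ends became −4.74 points with all peaks and passed 0.05, and the E2 effect turned to −0.355. The plain difference in this share between Y537S and WT libraries was −1.85 points at equal length (exact permutation p = 0.543, two-sided). With all peaks it became −5.89 points and passed 0.05 (exact permutation p = 0.0286). The difference between their Dox effects became −6.27 points with all peaks and did not (exact permutation p = 0.222).

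Shared Dox-gained regions numbered 326 at equal length, 892 at a −log10 q of 5 or more, 257 thinned (229 to 269 in 10 further draws), 686 with peaks over at least 50% of the region, 3410 without WT and 4758 without K303R. The real arrangement had the most regions in each. Shared lost regions numbered 158, 21, 63 and 8 (equal length, −log10 q of 5, thinned, summit windows), and 34, 12 and 976 without WT, Y537S and K303R. Shared E2-gained regions numbered 3 in summit windows and 16, 55 and 4 without WT, Y537S and K303R; E2-lost ones 1 when thinned and 6, 5 and 3. With fewer libraries more regions meet the rule by construction. Leaving out 1 library gave 2195 to 3870 shared Dox-gained, 4 to 43 lost, 0 to 4 E2-gained and 0 to 1 E2-lost regions.

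Within forms, equal length gave 3313 gained in WT and 1628 gained and 1661 lost in K303R. A −log10 q of 5 or more gave 4555 gained in WT and 5854 and 297 in K303R, and summit windows 255 lost in K303R. Thinning gave 2905 gained in WT, 9994 and 3035 in Y537S and 1919 and 1430 in K303R, and 39522 peaks per library 2751 gained in WT, 8490 and 5924 in Y537S and 1641 and 1673 in K303R. Leaving out 1 library gave 7370 to 18096 gained and 4149 to 14697 lost in WT, 31610 to 42490 and 15156 to 22383 in Y537S, and 15466 to 33760 and 397 to 2515 in K303R.

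The points by which E2 with Dox raised the share of Y537S-gained regions open were 29.8, 18.1 and 22.4 in WT (equal length, −log10 q of 5 or more, thinned) and 9.69, 11.9 and 8.01 in K303R. At equal length the Dox difference in open regions turned to −1.83 for FOXA1 and −0.667 for FKBP5. All 10 named shared Dox-gained regions and the 10 gained regions named in each form kept their pattern with equal length, both −log10 q thresholds and thinning. Of the 4 regions lost in every form 1 did at equal length and 0 in the others, and of the 10 lost in K303R 7 did at equal length and when thinned and 1 at a −log10 q of 10 or more. Of the 5 regions named as open with Dox+E2 alone, 3 in Y537S and 4 in K303R did when thinned. Depth limits all counts in that regions with a pileup under about 3 to 5 are in no list. Among gene lists, named regions and single genes, 192 values under an alternative stayed within the limits used here, 93 moved beyond them, mostly gene list counts with 20 kb windows or equal length, 5 lost their call before adjustment (GREB1, TFF1 and PGR at equal length, PGR and FKBP5 in matched pairs) and 2 changed sign, as given above.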

Other observations

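The tests in this part were chosen after the values were seen. Over the 16630 regions open in all 12 libraries, summit pileups were set relative to each library's own median and then to the mean of the libraries. On chromosome 8 (752 regions) the 4 K303R libraries had median log2 values of 0.28, 0.22, 0.27 and 0.26 (untreated, E2, Dox, Dox+E2), whereas the other 8 libraries lay between −0.15 and −0.03. On chromosome 6 (875 regions) the Y537S libraries lay between −0.25 and −0.23 and the others between 0.07 and 0.23. Each difference was separate in all libraries (exact permutation p = 0.00202 over 495 arrangements, adjusted 0.0348 over 69 tests). These arrangements treat the 4 libraries of a line as replicates, so the p-values describe lines. Chromosome 14 was higher in Y537S (0.22 on the log2 scale) and chromosome 15 higher in WT (0.18), with the same p.

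A hypothesis is that the engineered lines differ in copy number of these chromosomes, so that they may differ in more than the receptor they carry. Copy number would shift whole chromosomes in every treatment. On chromosome 8 the K303R difference was 0.35 on the log2 scale and all 12 bins of 10 Mb with at least 20 regions went the same way (0.22 to 0.58). These bins begin at position 30000001, so the start of the chromosome is not covered. On chromosome 6 the Y537S difference was −0.38 and all 16 bins went the same way (−0.49 to −0.33). The chromosome 8 difference also held between K303R and the WT libraries of the same run, which had −0.03 and −0.11. For Y537S differences such as that on chromosome 6, line and run cannot be told apart, since by the tags no other line shared its run. These values fit the hypothesis, but each form is 1 line and no DNA measurement was analysed here.

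On chromosome 19 the medians rose with Dox in each ER form: from −0.18 and −0.33 to −0.02 and 0.12 in WT, from 0.06 and 0.03 to 0.33 and 0.34 in Y537S, and from −0.05 and −0.14 to 0.03 and 0.03 in K303R (log2 scale, untreated and E2 against Dox and Dox+E2). On chromosomes 20 and 21 the medians also rose with Dox in every matched pair, so the rise was not particular to chromosome 19. These chromosomes were picked after their values were seen, and no difference was tested.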
